A study of Mus musculus with 12 samples.

How the data were processed

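Per the labels, Foxp3-positive regulatory T cells were taken from spleen and perigonadal fat of chow-fed C57BL/6 mice, controls with Foxp3-YFP-Cre and knockouts with Foxp3-YFP-Cre and floxed Tbx21, in 4 groups of 3 arrays. Per the labels, RNA was prepared with Qiagen Allprep, total RNA was amplified with NuGEN Ovation Pico WTA V2 and labelled with NuGEN Encore Biotin IL. The labels give the input as 5 pg, an amount whose unit could be a slip and was not checked here. The labels do not say how many animals each array holds. The array names in the labels begin with 1 of 3 long numbers, each shared by 4 arrays and read here as a slide. Each slide holds 1 array of every group, all of the same replicate, and was given the number of that replicate. On every slide the array name ends in A for spleen control, B for spleen knockout, C for fat control and D for fat knockout. If the letter is the place on the slide, group and place cannot be told apart, and a block for the slide does not remove this.

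The authors deposited a table with the mean bead intensity of 45281 probes per array, linear and not normalized, with a detection p-value for each probe and array per the file headers. The authors also deposited a table of normalized intensity, in which the 12 arrays share nearly all quantiles (medians of 107.119 to 107.249), and whose ranks are those of the same array in the other table (Spearman correlation 1). GenomeStudio is named in the authors' processing notes, and its version and the genome build are not given in the sources used here. No 2 arrays held identical values.

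The deposited bead intensities were corrected with nec of limma 3.58.1 in R 4.3.3, with the negative controls inferred from the deposited detection p-values and an offset of 16, then quantile normalized and set on the log2 scale. Kept were the 20367 probes with a detection p-value below 0.05 in at least 3 of the 12 arrays. By the platform annotation, 34885 probes had 1 gene symbol, 18 several and 10378 none. Symbols were updated through the Entrez number for 34807 probes, which changed 0. Of the kept probes 16470 had 1 symbol, and for each gene the probe with the highest mean over all arrays was used, which left 10025 genes. Probes with no symbol or several were left out of the counts, and the closing section gives those with none. As to precision, 27.0 to 40.9% of probes were detected per array. Where no probe of a gene was detected in the dimmer group, the fold is given as "at least", taken against the lowest detected signal of those arrays (4.83 to 5.53 on the log2 scale).

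A limma model with a mean per group was fitted to all 12 arrays (residual degrees of freedom 8, prior 3.88, from eBayes with default settings). It gave 6 comparisons: fat against spleen in each genotype, knockout against control in each tissue, the difference of the latter between tissues and their mean over tissues. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within a comparison, with no fold threshold. Members of gene lists were also adjusted over the list alone. SE is the moderated standard error. Principal component 1 held 36.3% of the variance and parted the tissues, and component 2 held 12.1%.

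Gene lists were written from general knowledge of the genes. They are Treg core, adipose Treg, resting lymphoid Treg, T-bet and type 1, type 2, type 17, Treg effector molecules, activation and checkpoint, immediate early and stress, homing and adhesion, lipid uptake and oxidation, sterol synthesis, glycolysis, oxidative phosphorylation, cell cycle, interferon response, MHC class II and antigen presentation, ribosomal proteins, and markers of T cells, CD8 and NK cells, B cells, macrophages and monocytes, dendritic cells, granulocytes and mast cells, adipocytes, stromal and mesothelial cells, endothelial cells, and erythroid cells and platelets. A further list of sex-linked genes only checked the samples. Of these genes Eif2s3y read 7.37 to 9.36 on the log2 scale over the 12 arrays. The 29 lists hold 459 genes, of which 340 were measured and 35 are in more than 1 list. The 27 lists with at least 3 measured members, sex-linked genes aside, were tested with camera of limma, with a preset correlation between genes of 0.01 and also with an estimated correlation, adjusted over the lists within each comparison. A gene counted as measured if it passed the filter, which detection in 1 tissue alone can meet. Members near background in 1 tissue could hardly be lower in the other, which tilts the counts and shifts of such lists. The alternative with no filter tested the same list members.

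The genes named were set by a rule. Per comparison they are the 10 with the largest rise and the 10 with the largest fall among called genes with the same sign on all 3 slides, up to 4 called members per list with the largest change (or the 2 with the smallest p where none passed), Tbx21 and Foxp3, and, where fewer than 5 genes passed, the 5 with the smallest p in each direction. Genes of unsure function could be left out. The comparisons, tests, lists, naming rule and first set of alternatives were fixed before the data were examined.

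The slide pairs arrays of different groups. Deviations from group means correlated at a median of 0.067 between arrays of the same slide (18 pairs, −0.0476 to 0.347) and −0.0413 between arrays of different slides, and the consensus correlation of limma with statmod 1.5.0 was 0.0526. A fixed block for the slide gave 642 calls in place of 646 for the tissues in control mice (560 of them shared), 623 in place of 579 in knockouts (537 shared), and the same counts of 1 and 0 for the comparisons of genotypes.

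The calls were tested on simulated data with 200 changed genes of 10025, a change of 1, 2 or 3 on the log2 scale. Noise had 1 spread per gene, pooled over the groups, with no tissue or slide effect. Real arrays of a group correlated less in fat (0.771 to 0.844) than in spleen (0.881 to 0.915). The shares and false calls below may therefore not hold for fat or spleen. For fat against spleen in controls, 7.46, 41.8 and 74.2% of the changed genes were recovered, and 4.48, 37.3 and 80.3% in knockouts. For knockout against control the shares were 5.97, 43.3 and 77.3% in fat, 4.48, 40.3 and 78.8% in spleen, and 14.9, 68.7 and 95.5% averaged over tissues. For the difference between tissues they were 0, 13.4 and 47.0%. False calls numbered 2 to 7 per comparison, the latter of 91 calls for knockout against control in fat, and no recovered gene had the wrong sign. Of 20 simulated lists of 15 genes, the 5 shifted were recovered in every comparison. With the preset correlation 2 others were called in the tissue comparison of controls and 0 elsewhere, and 0 with an estimated correlation. Noise was drawn for each gene on its own, so the simulated lists lack the correlation between genes that real lists can have. They do not test the list calls in that case.

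Alternatives were no background correction, normexp with an offset of 50, cyclic loess or median scaling in place of quantiles, the authors' normalized values, no filter or a stricter filter on dim probes (detection p-value below 0.01 in all 3 arrays of a group), every kept probe or the mean of a gene's probes, a fixed or random block for the slide, only the 2 groups compared, array weights, eBayes with trend and robust, a 2-fold threshold, and each array and each slide left out. After seeing the data, 3 were added: leaving out the fat array of each genotype highest in macrophage markers (fat control array 3 and fat knockout array 2), leaving out both spleen arrays of slide 3, and a replicate block within each tissue. Ranges and kept calls of named genes leave out the 2-group fits, the 2-fold threshold and the 3 added alternatives. Those of lists also leave out every kept probe and the mean of a gene's probes. For named genes and lists, all or every alternative below means those that remain. Where a list call changed, the estimated correlation and single arrays are named, and other alternatives changed some of these calls too. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.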

Results

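Regulatory T cells (Tregs) from perigonadal fat and spleen of chow-fed mice were profiled on 12 Illumina bead arrays in 4 groups of 3. Control mice carried Foxp3-YFP-Cre, and the libraries labelled T-bet knockout came from mice that carried it with a floxed Tbx21. Between 27.0 and 40.9% of the 45281 probes were detected per array, and 10025 genes were tested. Arrays of the same group correlated at 0.881 to 0.908 in spleen controls, 0.888 to 0.915 in spleen knockouts, 0.771 to 0.844 in fat controls and 0.823 to 0.842 in fat knockouts. All p-values below measure the spread between these samples, which may be technical. The number of arrays per group limits precision: the median standard error (SE) of a log2 fold change between 2 groups was 0.476.

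Tbx21, the gene for T-bet, was detected in some arrays of every group. Its 1 probe read 4.54, 4.88 and 5.19 on the log2 scale in the spleen controls and 4.69, 5.74 and 4.72 in the spleen libraries labelled T-bet knockout. In fat it read 5.50, 7.27 and 5.17 in the controls and 6.62, 7.57 and 4.94 in the knockouts, and it was detected in 2, 1, 2 and 2 of 3 arrays of these groups. The difference between genotypes was +0.40 in fat (limma adjusted p 0.9996) and +0.18 in spleen (adjusted p 1). Where the probe lies relative to the deleted part of the gene is unknown, so its signal does not check the labels. Foxp3, which defines the Treg lineage, had 3 detected probes, and the probe used averaged 7.74 in spleen controls, 8.04 in spleen knockouts, 8.24 in fat controls and 9.01 in fat knockouts. In the same order another probe, lower in fat, averaged 8.29, 8.38, 7.34 and 6.50, and the third 5.71, 5.32, 5.99 and 5.76. The 3 Foxp3 probes differed between genotypes by −0.23, +0.78 and −0.83 in fat, and none of the comparisons of Foxp3 passed.

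In control mice, type 2 cytokine genes were higher in the fat Treg libraries than in the spleen Treg libraries. Il5, the cytokine that drives eosinophils, rose by 7.50 on the log2 scale (SE 0.40, n = 3 per group, limma adjusted p 1.76e-06). It was undetected in all 6 spleen arrays, so the rise was at least 129-fold, a bound taken against the lowest detected signal of those arrays. Il13, a cytokine of the same locus, rose by 3.80 (SE 0.33, adjusted p 8.35e-05), and Gata3, the transcription factor that activates both, rose by 2.94 (SE 0.45, adjusted p 0.00276). Hdc, which makes histamine, rose by 6.45 (SE 0.51, adjusted p 5.15e-05), and Csf2, a myeloid growth factor, rose by 5.79, at least 41.2-fold. Of the 10 measured type 2 genes, 5 rose and none fell, and 6 rose when adjusted over the list alone. The chemokine receptor Ccr8 (+2.63, adjusted p 0.0143) was among them, and its call was lost without spleen control array 1 (adjusted p 0.0609, with 0.00237 to 0.207 over all alternatives). The list mean was higher by 2.29 (camera adjusted p 1.19e-07, at most 0.0046 over the alternatives with a list test). The list averaged 5.29 in spleen controls, within the range of the lowest detected signals (4.83 to 5.53). Its members thus had little room to fall.

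**Figure D1:**
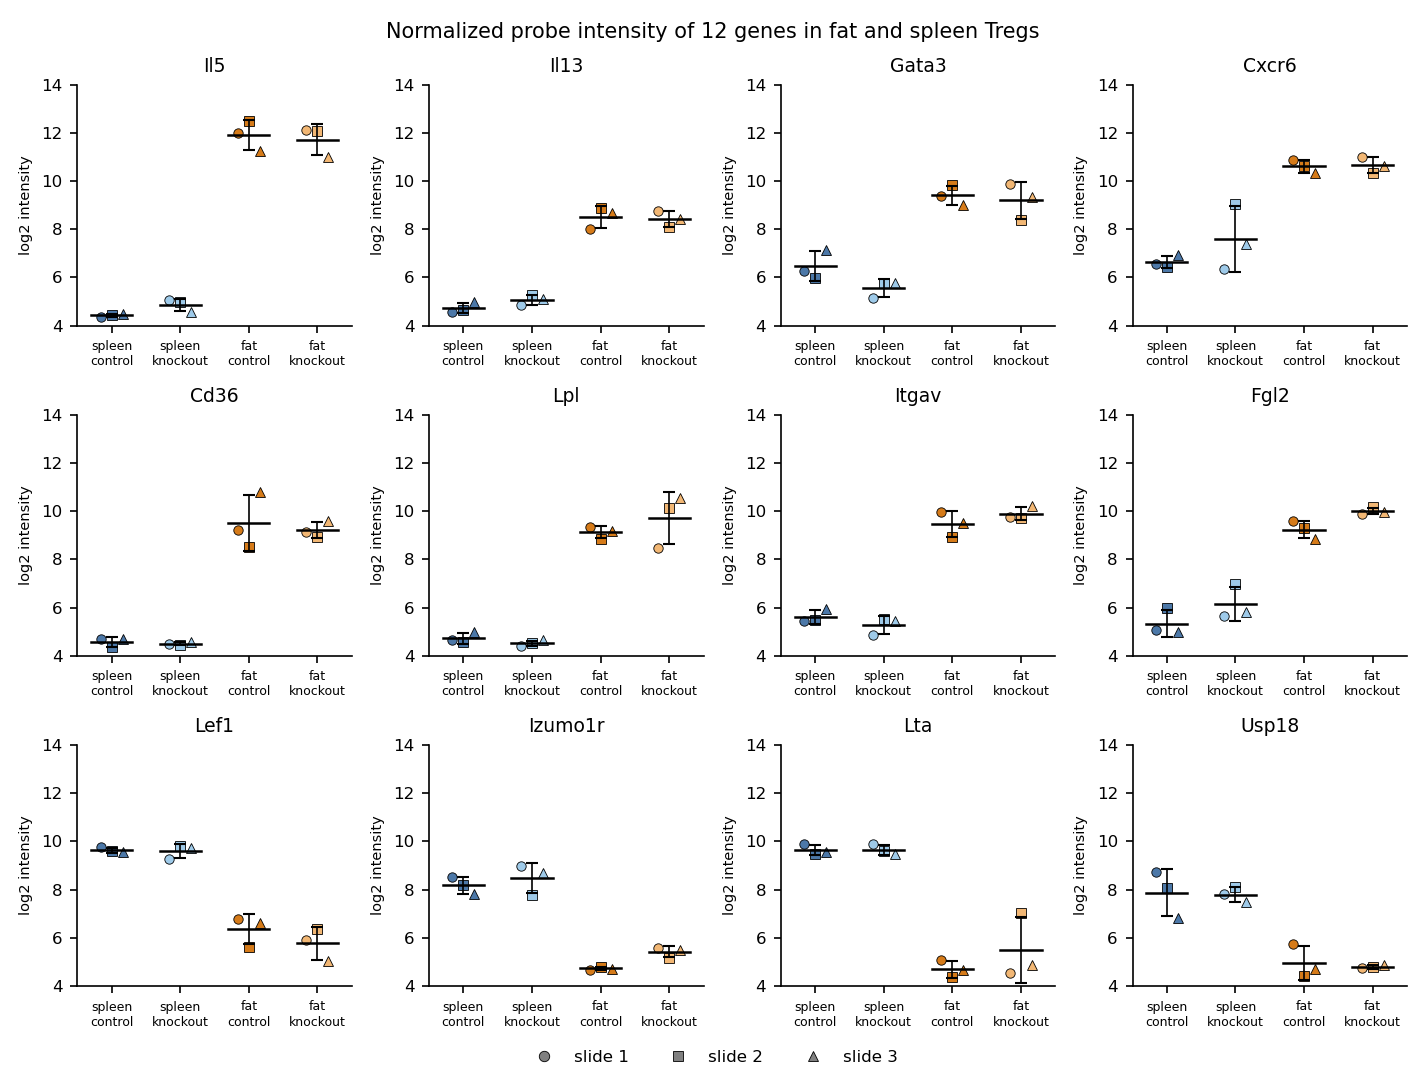
Normalized log2 intensity of 12 genes in each array, with the mean and standard deviation of each group (n = 3). Symbols mark the slide.

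The list of genes known from adipose Tregs held the broadest change. Of its 22 measured members 16 rose, 19 when adjusted over the list alone, and none fell. Among them were genes of lipid handling: Dgat1, which makes triglycerides, rose by 5.08 (SE 0.48, adjusted p 0.00013), Cd36, a fatty acid transporter, by 4.92 (SE 0.48, at least 24.3-fold), and Lpl, which releases fatty acids from lipoproteins, by 4.41 (SE 0.46). The chemokine Cxcl2 (+6.76), the chemokine receptor Cxcr6 (+3.97), the nuclear receptor Rora (+3.89) and the integrin subunit Itgav (+3.86) rose too. The calls of these 7 genes were kept under every alternative that followed named genes. The 4 other kept probes of Itgav rose less and did not pass (+0.78 to +1.60, adjusted p 0.277 to 0.581). Il10, a suppressive cytokine, rose by 4.23 (SE 0.87, adjusted p 0.0132). Its call was lost without spleen control array 1 (0.0637) or spleen control array 2 (0.0599), and its adjusted p ran from 0.0025 to 0.189 over all alternatives. The list mean was higher by 2.98 (camera adjusted p 3.45e-23, at most 0.00157). The 2 measured adipocyte markers also averaged higher in fat controls (7.06) than in spleen controls (4.64). Adipocyte RNA was not tested as a source of the lipid genes. Cd36 also followed the macrophage markers over the fat arrays (slope 0.81).

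Effector and lipid genes moved in the same comparison. Among 15 Treg effector molecules 8 rose and none fell, and 8 rose and 1 fell when adjusted over the list alone. They included Fgl2, a secreted suppressor of T cells (+3.90, SE 0.41, adjusted p 0.000265), Furin, a protease that processes TGF-beta (+4.54), and the lectin Lgals3 (+3.58). The list mean was higher by 1.52 (camera adjusted p at most 0.00786). Of 20 lipid uptake and oxidation genes 7 rose and 1 fell, with the same counts when adjusted over the list alone (mean +1.34, camera adjusted p 0.000189, at most 0.0268). Of 25 activation and checkpoint genes 4 rose, 13 when adjusted over the list alone, among them the nuclear receptor Nr4a3 (+3.13, adjusted p 0.00345). The mean of that list was higher by 1.13 (camera adjusted p at most 0.0046). Of 21 homing and adhesion genes 4 rose, and 6 rose and 2 fell when adjusted over the list alone. That list did not shift (mean +0.58, camera adjusted p 0.0556), but passed in 7 of 27 alternatives. These include leaving out spleen knockout array 2 (0.0457) or spleen control array 3 (0.0489).

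Some genes of resting lymphoid T cells were lower in fat, among other genes. Lef1, a transcription factor of naive T cells, fell by 3.29 (SE 0.41, adjusted p 0.000684), and Izumo1r, the folate receptor of Tregs, fell by 3.44 (SE 0.35, adjusted p 0.000245). The receptor Gpr83 fell by 3.63 (at least 8.56-fold), Lta, the cytokine lymphotoxin alpha, fell by 4.94, and Dtx1, a regulator of Notch signalling, fell by 3.93. All 5 calls were kept under every alternative that followed named genes. Of the 5, only Lef1 is in the resting lymphoid list. Izumo1r and Gpr83 are in the Treg core list, and Lta and Dtx1 are in no list. Other kept probes of these genes were lower by less: 1 of 3 passed for Lef1 (−3.10, −1.52 and −1.36), and none for Izumo1r (−1.07 to −2.05), Gpr83 (−1.07) and Lta (−0.85). Of 14 resting lymphoid Treg genes 3 fell, and 6 fell and 1 rose when adjusted over the list alone. The list mean fell by 1.19 (camera adjusted p 0.000814), a call lost with an estimated correlation (adjusted p 0.113). Among 18 interferon response genes 3 fell, 4 when adjusted over the list alone, with Usp18, which restrains interferon signalling, down the most: it fell by 2.92 (adjusted p 0.00413), while its other probe was at −1.40 (adjusted p 0.249). That list mean fell by 0.80 (camera adjusted p 0.00212, at most 0.0441).

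Treg core genes did not move together in control mice: 2 of 17 fell (Gpr83 and Izumo1r), and 5 rose and 3 fell when adjusted over the list alone. The mean was −0.20 but the median +0.40 and the test pointed up (camera adjusted p 0.541). Of 19 T-bet and type 1 genes 3 rose, 5 when adjusted over the list alone, including Stat4, which relays interleukin 12 signals (+1.80, SE 0.32, adjusted p 0.00616). The mean of that list was higher by 1.00 (camera adjusted p 0.000614), a call lost with an estimated correlation (adjusted p 0.113). Of 6 type 17 genes only Rora rose (list mean +0.71, camera adjusted p 0.143). No gene of glycolysis (mean +0.31, camera adjusted p 0.0947), the cell cycle (−0.27, 0.409) or sterol synthesis (−0.01, 0.930) passed, and for sterol synthesis the median was −0.30 while the test pointed up. Of 23 oxidative phosphorylation genes 1 fell (mean −0.35, camera adjusted p 0.0545). The list passed in 9 of 27 alternatives, among them without fat control array 2 (0.0327) or spleen control array 3 (0.0273). Of 17 ribosomal protein genes 1 fell (mean −0.45, camera adjusted p 0.0352), a call lost with an estimated correlation (adjusted p 0.113). In all it was lost in 9 of 27 alternatives, among them without fat control array 1 (0.0666), fat control array 3 (0.0632), spleen control array 1 (0.0611) or spleen control array 2 (0.0789).

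Markers of macrophages were higher in the fat libraries as well. Of 16 macrophage and monocyte markers 7 rose in control mice, 10 when adjusted over the list alone, among them the scavenger receptor Cd163 (+4.40, SE 0.86, adjusted p 0.00996, with another probe at +2.02, adjusted p 0.235), lysozyme Lyz2 (+4.05) and the lipoprotein Apoe (+3.83). MHC class II genes, which present antigen on such cells, moved beside them: 3 of 10 rose, 8 when adjusted over the list alone, led by H2-Eb1 (+4.40, SE 0.58, adjusted p 0.000986). The means of both lists were higher, by 2.25 and 1.97, and both calls were lost with an estimated correlation (adjusted p 0.145 and 0.147). Immediate early and stress genes were higher by 1.97 on average, with 3 of 20 up, 5 when adjusted over the list alone. These included Ier3 (+5.59) and Atf3 (+4.03), and this list's call was also lost with an estimated correlation (adjusted p 0.189). The immediate early difference was 2.42 on slide 1, 2.45 on slide 2 and 1.03 on slide 3, where both spleen arrays were high.

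Few single markers of other cell types passed in control mice, though 3 of these lists shifted. Of 9 granulocyte and mast cell markers 1 rose, the protease Cpa3 (+1.82, adjusted p 0.0118), with a list mean of +1.52 (camera adjusted p 0.000814, at most 0.0268). These markers averaged 4.72 in spleen controls, near background, so they had little room to fall. Of 10 CD8 and NK cell markers 1 rose, 3 when adjusted over the list alone. That list was higher by 1.04 (camera adjusted p 0.0104), a call lost with an estimated correlation (adjusted p 0.228) or without fat control array 3 (0.212). T cell markers fell by 0.61 with 1 of 12 passing, 2 when adjusted over the list alone (camera adjusted p 0.0261), a call lost with an estimated correlation (adjusted p 0.106) or without fat control array 3 (0.0769). B cell (+0.36, camera adjusted p 0.319), dendritic cell (+0.84, 0.0945), endothelial (+0.98, 0.118) and stromal and mesothelial markers (+1.30, 0.0869) held no gene that passed. The dendritic list passed without fat control array 2 (0.0467), and the stromal list without fat knockout array 2 (0.0352) or fat control array 3 (0.044). Among 3 erythroid and platelet markers Pf4 rose (+4.65), while the other members were lower on average. The list had a mean of −0.30 and a test that pointed up (camera adjusted p 0.967). Of the 2 measured adipocyte markers, too few to test, the fatty acid carrier Fabp4 rose (+4.83, adjusted p 0.0155), a call lost without spleen control array 1 (0.0625) or spleen control array 2 (0.0582), with up to 0.21 over all alternatives.

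**Figure D2:**
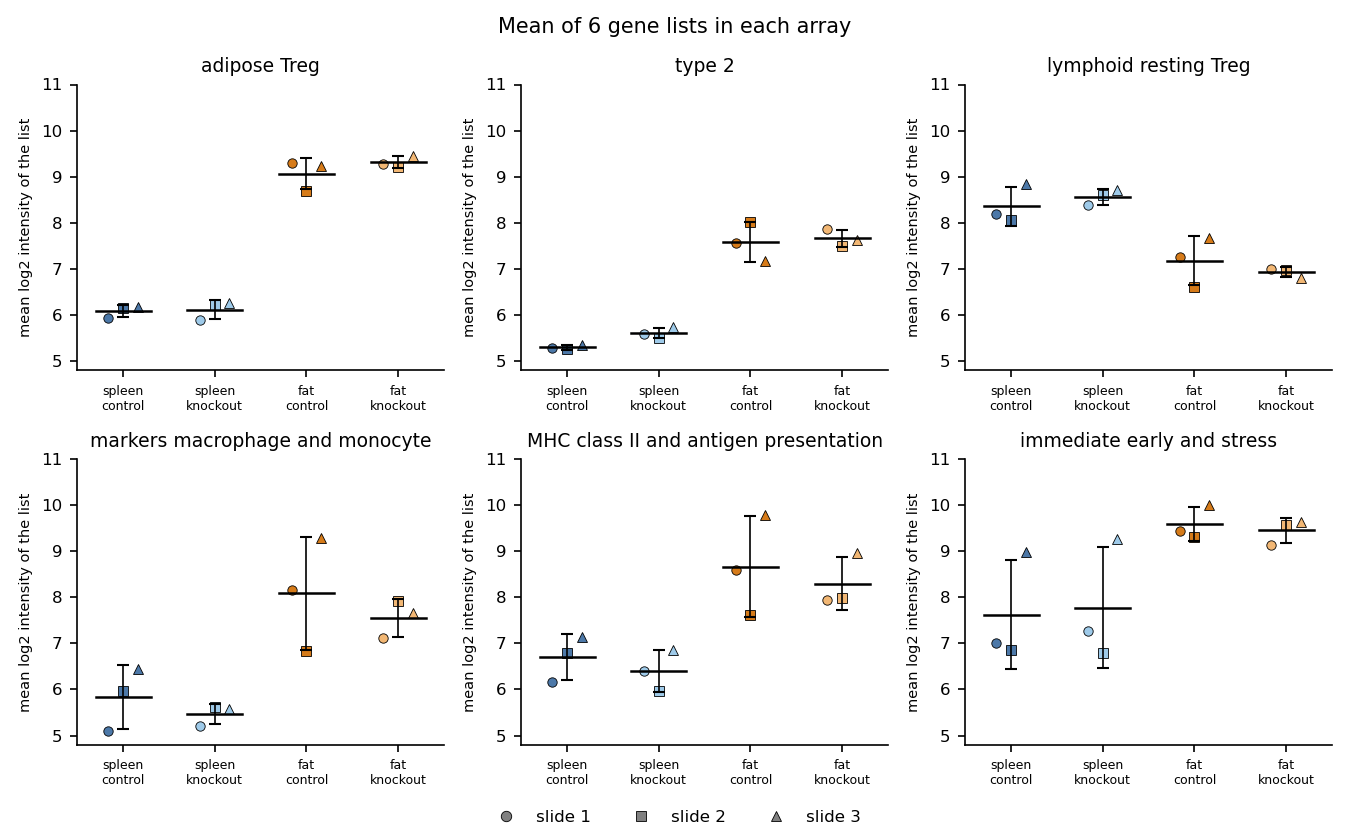
Mean log2 intensity of 6 gene lists in each array, with the mean and standard deviation of each group (n = 3). Symbols mark the slide.

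Across all genes in control mice, limma called 646, of which 367 were higher and 279 lower in fat. All 646 differed at least 2-fold. The higher share of 56.8% became 68.3% with cyclic loess (398 higher, 185 lower) and 73.8% with median scaling (389 higher, 138 lower). Median scaling also moved the median fold change of all genes from −0.065 to +0.042. The count fell to 318 without spleen control array 1 and to 355 without spleen control array 2. Of the 64 called genes that the naming rule picked, 43 kept their call without any 1 array. Another probe of the same gene pointed the other way for 28 of the 272 called genes that had one, and none of these was called the other way. With a block for the slide, the call of Relb, a subunit of NF-kappa-B, was lost (+1.63, adjusted p 0.0439, with the block 0.0682, and 0.0213 to 0.233 over all alternatives). Leaving out any 1 array except fat knockout array 1 or 3 lost it too (0.0523 to 0.167). With the block the call of Srebf2, which drives sterol synthesis, was gained (+1.97, adjusted p 0.0523, with the block 0.04, and 0.034 to 0.255 over all alternatives), as it was without fat knockout array 1 (0.034) or 3 (0.0457).

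The libraries labelled T-bet knockout differed between tissues in many of the same genes. Il5 rose by 6.85 (SE 0.40, n = 3 per group, limma adjusted p 4.91e-06, at least 90.6-fold), Il13 by 3.35 (SE 0.33, adjusted p 0.000201) and Gata3 by 3.63 (SE 0.45, adjusted p 0.000739). Lpl rose by 5.19 (at least 22.6-fold), Cd36 by 4.71 (at least 16-fold), Dgat1 by 4.66, Itgav by 4.62 and Rora by 3.57, and of the 4 other probes of Itgav 1 passed (+3.44) and 3 did not (+1.53 to +1.82). Of the 22 adipose Treg genes 18 rose, 21 when adjusted over the list alone (mean +3.21, camera adjusted p 1.15e-28, at most 0.000722). Of 10 type 2 genes 5 rose, 6 when adjusted over the list alone (mean +2.06, camera adjusted p at most 0.00632). Of 15 effector molecules 7 rose and 1 fell, 9 and 1 when adjusted over the list alone. They included Fgl2 (+3.86), Furin (+4.49), Lgals3 (+4.71) and the cytotoxic protease Gzmb (+2.72, at least 4.22-fold), with a list mean of +1.67 (camera adjusted p at most 0.00548). Of 20 lipid genes 7 rose, 8 with 1 lower when adjusted over the list alone (mean +1.48, camera adjusted p at most 0.0133). The adipocyte markers averaged 7.11 in fat knockouts and 4.89 in spleen knockouts, and adipocyte RNA was not tested as a source here either.

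Activation genes were higher in knockout fat and resting genes lower. Of 25 activation and checkpoint genes 7 rose, 18 with 1 lower when adjusted over the list alone, including Nr4a3 (+2.89, adjusted p 0.00591), and the list mean was higher by 1.18 (camera adjusted p at most 0.00386). Lef1 fell by 3.82 (SE 0.41, adjusted p 0.000271), Ccr7, which guides T cells to lymph nodes, fell by 2.33 (adjusted p 0.00343), and Izumo1r fell by 3.05 (adjusted p 0.00047). Dtx1, which like Izumo1r is not in the resting lymphoid list, fell by 4.08 (at least 12.6-fold). Of the 3 other probes of Lef1 1 passed (−3.01), and none of the 3 of Izumo1r did (−1.40 to −2.06). Of 14 resting lymphoid genes 5 fell and 1 rose, 10 and 1 when adjusted over the list alone (list mean −1.64, camera adjusted p at most 0.0454). Of 18 interferon response genes 3 fell, 4 when adjusted over the list alone, led by Usp18, which fell by 3.00 (at least 6.29-fold, list mean −0.91, camera adjusted p 0.00313, at most 0.0454). Of 17 ribosomal protein genes 2 fell, among them Rpl22, which fell by 1.99 (list mean −0.68, camera adjusted p 0.00171, at most 0.0429). Of 17 Treg core genes 4 rose and 3 fell, 7 and 5 when adjusted over the list alone (mean +0.12, camera adjusted p 0.101). The list passed in 5 of 27 alternatives, among them without spleen knockout array 1 (0.0356).

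Type 1 and innate markers also differed between tissues in the knockouts. Of 19 T-bet and type 1 genes 4 rose, also 4 when adjusted over the list alone, among them Hopx, a transcriptional cofactor of effector cells (+2.44, adjusted p 0.00194). The mean of that list was higher by 0.76 (camera adjusted p 0.00202), a call lost with an estimated correlation (adjusted p 0.173). Macrophage markers (6 of 16 up, 11 when adjusted over the list alone, mean +2.09) and MHC class II genes (4 of 10 up, 6 when adjusted over the list alone, mean +1.90) moved together again. Both calls were lost with an estimated correlation (adjusted p 0.174 and 0.173). Lyz2 rose by 3.75 and H2-Eb1 by 3.83. Immediate early genes were higher by 1.68 with 3 of 20 up, again including Ier3 (+5.34), a call lost with an estimated correlation (adjusted p 0.269), and by 1.87, 2.78 and 0.38 on slides 1, 2 and 3.

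Homing genes differed in both directions in the knockouts, and the remaining lists showed few calls. Of 21 homing genes 5 rose and 2 fell, 6 and 4 when adjusted over the list alone (mean +0.30, camera adjusted p 0.345), and of 6 type 17 genes 1 rose and 1 fell (camera adjusted p 0.221). Among sterol synthesis genes 1 rose (camera adjusted p 0.817), and no gene of oxidative phosphorylation (0.0529), glycolysis (0.180) or the cell cycle (0.444) passed. The oxidative phosphorylation list passed in 6 of 27 alternatives, among them without fat knockout array 2 (0.0444) or spleen knockout array 1 (0.0336). CD8 and NK markers (2 of 10 up, 3 when adjusted over the list alone, mean +0.97, camera adjusted p 0.0155), granulocyte and mast cell markers (none of 9, mean +1.32, 0.0309) and T cell markers (none of 12, mean −0.49, 0.0319) lost their calls with an estimated correlation (adjusted p 0.297, 0.1 and 0.1). In that order, the 3 calls were lost in 4, 8 and 10 alternatives, some of which left out a single array. Without fat knockout array 3 the CD8 and NK list and the T cell list both gave 0.0549, and without fat knockout array 2 the granulocyte list gave 0.108. Without spleen knockout array 3 the T cell list gave 0.0651 and the granulocyte list 0.0556. B cell (camera adjusted p 0.728), dendritic (0.697), endothelial (0.412), erythroid and platelet (0.966) and stromal markers (0.119) did not shift, with Pf4 up (+3.86), and 1 of the 2 adipocyte markers rose. That gene was again Fabp4 (+4.61, adjusted p 0.0203), whose call was lost without fat knockout array 1 (0.0649) or 2 (0.0686) and without spleen knockout array 1 (0.069), 2 (0.0712) or 3 (0.0587), with up to 0.272 over all alternatives.

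In all, limma called 579 genes between the tissues of the knockouts, 340 higher and 239 lower in fat, each by at least 2-fold. The higher share of 58.7% was 68.7% with cyclic loess (375 higher, 171 lower) and 77.1% with median scaling (397 higher, 118 lower), which moved the median of all genes from −0.083 to +0.086. The count fell to 305 without spleen knockout array 1 and to 306 without spleen knockout array 2. Of the 68 called genes that the naming rule picked, 42 kept their call without any 1 array. With a block for the slide, the call of Nt5e, which makes adenosine, was lost (−1.64, adjusted p 0.0483, with the block 0.0641, and 0.0138 to 0.257 over all alternatives). Leaving out any 1 array except fat control array 1 or 2 lost it too (0.0536 to 0.173).

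The tissue differences of the genotypes overlapped. Among the genes called, 256 were higher in fat in both genotypes, against 12.4 in independent lists of these sizes, and 110 were lower in both, against 6.65. Both comparisons come from the same fit, with the same variance per gene and the same probe filter. The real lists are thus not independent, and these expected counts test nothing. No gene was called in opposite directions. Of the 859 genes called in either genotype, such as Il5, Lpl and Lef1, 833 had the same sign in both, and their fold changes correlated at 0.907 (0.730 across all genes). The 859 were picked for a large difference in at least 1 genotype, which by itself raises both values. None of the 859 genes passed the interaction test for a tissue difference that differed between genotypes. That test recovered at most 47.0% of simulated changes, so it does not show that the tissue differences are equal.

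**Figure D3:**
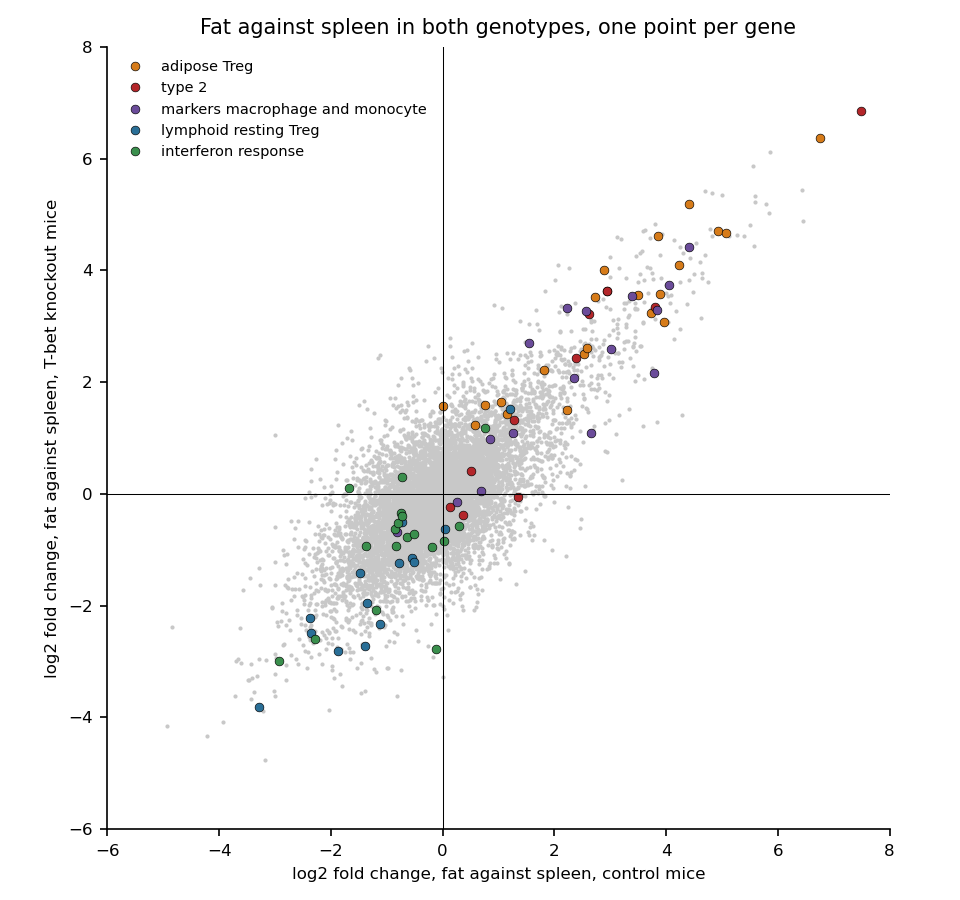
Log2 fold change between fat and spleen in control mice against that in T-bet knockout mice, 1 point per gene tested, with the members of 5 gene lists in colour.

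Between genotypes in fat, 1 gene passed. Slc10a7, which takes part in calcium handling, was higher by 2.85 in the libraries labelled T-bet knockout (SE 0.34, n = 3 per group, limma adjusted p 0.0223). Its probe was detected in none of the 3 control and all 3 knockout fat arrays, and the difference was positive on each slide. The size of the difference is not exact, since the control signal was not above background, and no bound is given because other probes of the gene were detected there. Its adjusted p ran from 0.00601 to 0.772 over the alternatives, and with a block for the slide it was 0.0352. With a replicate block within each tissue 0 genes were called. The call was lost without any of 9 single arrays: fat control array 1 (0.0527) or 3 (0.0875), fat knockout array 1 (0.0558) or 3 (0.091), spleen control array 2 (0.0557) or 3 (0.0531) and spleen knockout array 1 (0.0625), 2 (0.0589) or 3 (0.0688). The other 2 probes of Slc10a7 differed by −0.05 and −0.85, and the mean of its probes gave an adjusted p of 0.772. At an unadjusted p below 0.05, limma gave 695 genes, with 501 expected by chance, and 424 to 1294 under the alternatives. The fit shares 1 spread per gene over all groups, while fat arrays varied more than spleen arrays. The test can thus be too lenient in fat, and 695 against 501 does not show an excess. The next smallest p-values among higher genes, none of them passing, belonged to Ripply3 (+2.35, adjusted p 0.0888), Aldh5a1, which breaks down GABA (+2.84, 0.108), the kinase Map3k20 (+2.11, 0.108) and Crip2 (+2.05, 0.112). Among lower genes they belonged to C030034I22Rik (−1.80, 0.112), Radx, a replication fork protein (−2.43, 0.174), the mitochondrial kinase Dguok (−2.17, 0.220), Armcx3 (−2.15, 0.220) and Eid1 (−1.77, 0.220). Leaving out 1 array gave other calls: Selp without fat control array 1 (−3.05, adjusted p 0.0455), Map3k20 without fat knockout array 1 (+2.48, 0.0454), Blm (−2.70) and Mospd2 (−2.38) beside Slc10a7 without fat control array 2 (each 0.045), and Cd300lg without fat control array 3 (−3.91, 0.00568). Selp, Blm, Mospd2 and Cd300lg were chosen after their values were seen.

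T-bet and type 1 genes did not shift as a list in fat. The 19 T-bet and type 1 genes had a mean difference of −0.38 (camera adjusted p 0.662, and −0.83, +0.18 and −0.50 on slides 1, 2 and 3), and none passed. When adjusted over the list alone 2 were higher. Gzmb was at +1.22 (SE 0.34, adjusted p 0.399) and Eomes, a T-box factor related to T-bet, at +1.94 (adjusted p 0.405), both positive on all 3 slides. Lower values, none passing, were those of Ccl3 (−2.28, adjusted p 0.623), Tnf (−1.84, 0.540) and Ifng (−1.53, 0.932), negative on all 3 slides, and of Ccl4 (−1.86, 0.932) and Cxcr3 (−1.78, 0.707), negative on slides 1 and 3. These 5 genes were chosen after their values were seen. Adipose Treg genes (+0.25, camera adjusted p 0.222), type 2 genes (+0.08, 0.697), effector molecules (+0.30, 0.177) and lipid genes (+0.01, 0.994) did not shift. Treg core genes were higher by 0.40 (camera adjusted p 0.0319, and +0.36, +0.58 and +0.26 on slides 1, 2 and 3) with no member passing, a call lost with an estimated correlation (adjusted p 0.671). It was lost in 10 of 27 alternatives, among them without fat knockout array 1 (0.309) or 2 (0.127) and without fat control array 1 (0.165) or 3 (0.206). Macrophage markers fell by 0.53 (camera adjusted p 0.0319, with −1.06, +1.09 and −1.62 on slides 1, 2 and 3), a call lost with an estimated correlation (adjusted p 0.735). It was lost in 9 of 27 alternatives, among them without fat knockout array 1 (0.336) or 3 (0.0566) and without fat control array 1 (0.165) or 3 (0.976), where the mean was +0.07. Without fat control array 2, MHC class II genes fell by 0.90 (camera adjusted p 0.00273) and resting lymphoid genes fell by 0.53 (0.0184). Both calls use the preset correlation, and with an estimated correlation over all arrays these lists gave an adjusted p of 0.803 and 0.735.

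**Figure D4:**
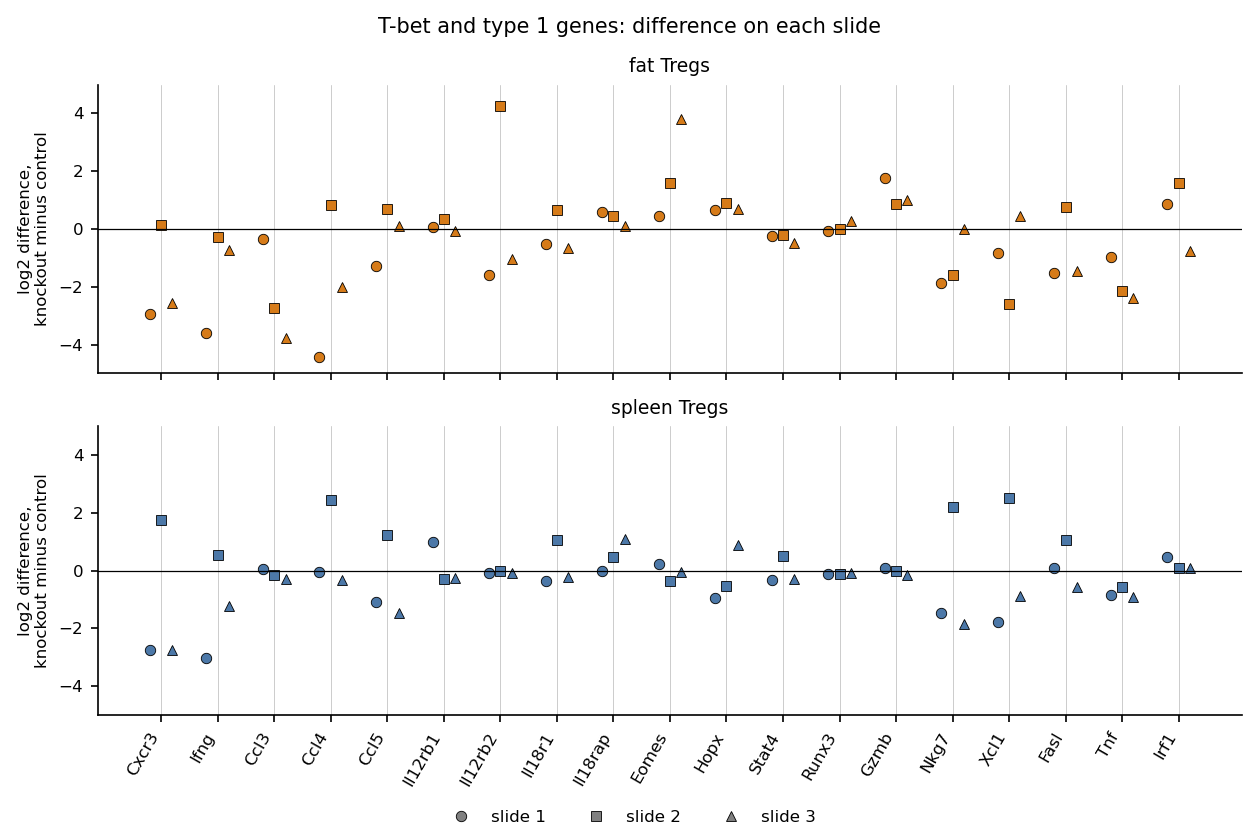
Difference in log2 intensity between the knockout and control array of each slide for 19 T-bet and type 1 genes, in fat and in spleen.

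In spleen, limma called no gene between genotypes, and 0 or 1 under the alternatives. With limma, 219 genes had an unadjusted p below 0.05, against 501 by chance and 117 to 697 under the alternatives. The spread shared with the more variable fat arrays can make this test too strict. The 501 is thus not exact here, and 219 does not show an absence of differences. The values nearest to passing (all adjusted p 1) were Boc (+1.60), Smim24 (+2.05), Rbm6 (+1.82), Dtwd1 (+1.01) and AU020206 (+1.00) among higher genes. Among lower genes they were Rreb1 (−2.05), Zfp41 (−1.42), Hivep3 (−1.23), Afp (−1.43) and Xpo4 (−1.06). Cxcr3, a chemokine receptor that T-bet activates, was at −1.24, with −2.75, +1.77 and −2.74 on slides 1, 2 and 3, and the inflammatory cytokine Tnf was at −0.77. The T-bet and type 1 list had a mean of −0.14 (camera adjusted p 0.832, with −0.57, +0.63 and −0.48 on slides 1, 2 and 3), and no list passed (lowest camera adjusted p 0.301). Leaving out 1 array gave list calls: immediate early genes without spleen knockout array 2 (+0.65, camera adjusted p 0.0101) or spleen control array 3 (+0.84, 8.77e-05), and without spleen control array 1 the macrophage markers (−0.74, 0.000391) and MHC class II genes (−0.56, 0.0396). These calls use the preset correlation, and with an estimated correlation over all arrays the 3 lists each gave an adjusted p of 0.942. Both spleen arrays of slide 3 were high in immediate early genes, so leaving out spleen control array 3 leaves that slide in the knockouts only.

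No gene passed the test for a genotype difference that itself differed between fat and spleen. The median SE was 0.673 here. In simulated data this test recovered 0, 13.4 and 47.0% of changes of 1, 2 and 3, so real differences can be missed. With limma the smallest adjusted p was 0.319, shared by Aldh5a1 (+3.59), Slc10a7 (+2.85), Acadm, an enzyme of fatty acid oxidation (+2.81), and Ripply3 (+2.69). At an unadjusted p below 0.05 there were 382 genes (299 to 779 under the alternatives), and the alternatives called 0 or 1. No list passed (lowest camera adjusted p 0.358). Without fat control array 2 the resting lymphoid (−0.74, 0.0101) and macrophage lists (−0.79, 0.00337) did, and without spleen control array 3 the resting lymphoid (−0.70, 0.0376) and immediate early lists (−0.97, 0.00794) did. These calls use the preset correlation, and with an estimated correlation over all arrays the 3 lists gave an adjusted p of 0.832, 0.944 and 0.944.

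Averaged over tissues, limma called no gene between genotypes either. There were 414 genes at an unadjusted p below 0.05 (316 to 818 under the alternatives, with 0 or 1 called), and the smallest adjusted p was 0.672, for Slc10a7 (+1.42). Cxcr3 was at −1.51 and Tnf at −1.31 (both adjusted p 0.999), Tnf with the same sign on all 3 slides. The T-bet and type 1 list had a mean of −0.26 (camera adjusted p 0.501). Macrophage markers fell by 0.45 (camera adjusted p 0.00417), a call lost with an estimated correlation (adjusted p 0.607) or without fat knockout array 1 (0.114), fat control array 3 (0.429) or spleen control array 3 (0.0928). Treg core genes were higher by 0.24 (camera adjusted p 0.0402), a call lost with an estimated correlation (adjusted p 0.607). It was lost in 13 of 27 alternatives. These include leaving out fat knockout array 1 (0.149) or 2 (0.165), fat control array 1 (0.0835) or 3 (0.301), spleen knockout array 1 (0.209) or 3 (0.0663), or spleen control array 3 (0.114). MHC class II genes had a mean of −0.33 (camera adjusted p 0.0969), and passed with a block for the slide (0.0349), without fat control array 2 (0.000708), fat knockout array 3 (0.0107), spleen control array 1 (0.021) or spleen knockout array 3 (0.046). Effector molecules (+0.23, camera adjusted p 0.0969) passed in 7 of 27 alternatives, among them without fat control array 2 (0.0362) or spleen knockout array 2 (0.0246). With an estimated correlation over all arrays, the MHC class II and effector lists each gave an adjusted p of 0.607.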

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

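The tests in this part were chosen after the results were seen. Probes with no gene symbol were not part of the counts of genes, and 3897 of them were kept. Between fat and spleen, 111 of these were called in control mice (68 higher in fat, 43 lower) and 110 in T-bet knockout mice (61 higher, 49 lower). Between genotypes in fat 1 was called. They stand out because they carry a signal that the gene counts leave out, and what they measure was not tested.

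Macrophage markers and adipose Treg genes were both higher in fat. Over the 6 fat arrays, the median slope of each marker on the mean of the others was 0.944 (0.797 without the 2 extreme arrays), which is consistent with macrophage RNA in the fat sorts. Of the 3 MHC class II genes that rose in controls (median slope 0.858), H2-Aa had a slope of 0.858 and H2-Ab1 of 1.12, in line with that source but also with other cells that present antigen, since B cell (7.27) and dendritic markers (7.63) were also highest, among fat controls, in array 3. H2-Eb1 had a slope of 0.126, so its rise stays open. Adipose Treg genes that rose had a median slope of 0.174 and the type 2 genes that rose one of −0.490, which that source does not predict. For Il5, Il13 and Hdc, 5 of 13 listed mast cell and basophil markers were measured, each detected in 3 or 4 of the 6 fat arrays. Their median rise was 0.332 in knockout mice, against 3.35 for Il13, the smallest rise of the 3 genes. In control mice it was 0.747, against 3.80, and Cpa3 was called there (+1.82, limma adjusted p 0.0118). The markers rose less than the 3 genes, but signals near background can understate a rise. This test therefore cannot exclude RNA of those cells. Cells other than macrophages, mast cells and basophils were not tested as a source.

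Immediate early genes were higher in fat, and also in the spleen arrays of slide 3. There the list mean lay above that of slides 1 and 2 by 2.04 in control mice and by 2.23 in knockouts, which is in line with handling or a batch shared by these arrays. Within slides 1 and 2 alone, fat lay above spleen by at least 1.87. The rise on slide 3 makes the difference between tissues smaller there by construction, so this value tests no cause of it. Fat and spleen also differ in how cells are prepared, which these arrays cannot part from the tissue.

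The T-bet and type 1 list did not shift between the labelled genotypes, and in spleen 8 of its 19 genes, Cxcr3 and Ifng among them, were positive on slide 2 and negative on slides 1 and 3. Slide 1 or 3 alone differed in sign for 4 and 2 genes, and 5 genes, Tnf among them, had 1 sign throughout. A swap of the spleen labels of slide 2 was tested across genes: the higher of its correlations with slides 1 and 3 was −0.0124, which decides nothing, and exchanged labels gave 197 genes at an unadjusted p below 0.05 in place of 219. Ccl3, Ccl4 and Tnf were lower in knockout fat on most slides, without passing. Their median slope on the macrophage markers was 0.769 over the 6 fat arrays (Ccl3 0.77, Ccl4 1.65 and Tnf 0.032) but 0.089 without the 2 extreme arrays, so macrophage RNA as a source stays open for Ccl3 and Ccl4. For Tnf the slope gives no sign of it, and on slide 2 Tnf (−2.16) and Ccl3 (−2.74) were lower in knockout fat while the macrophage markers were higher (+1.09).

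Other splits of the same arrays were counted. With 10 splits of 6 arrays the share can never be under 0.1. Fat against spleen gave 646 genes called in controls and 579 in knockouts, and the highest other split gave 1 in each (1 of 10 splits as large). At an unadjusted p below 0.05, knockout against control gave 695 genes in fat, and the highest other split gave 965, one that keeps 2 slide pairs together (7 of 10 as large, and 704 at most among the splits that part all 3 slides). In spleen the values were 219 and 657, a split that nearly follows slide 3 (6 of 10 as large, and 197 at most among the splits that part all 3 slides). Of 100 splits drawn from 200, 92 reached the 382 genes of the difference between tissues (highest 1025), and 82 reached the 414 genes of the average (highest 1186).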

How the results depend on the processing

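The alternatives that leave out arrays because of their macrophage or immediate early genes, and the replicate block within each tissue, were chosen after the result was seen. Apart from leaving out single arrays or slides, fat against spleen had 380 to 950 genes or probes called in control mice and 381 to 923 in knockouts. In controls the count of 646 was 380 with only the 2 groups compared and 417 without both spleen arrays of slide 3. In knockouts the count of 579 was 923 with every kept probe tested and 381 without both spleen arrays of slide 3. Fewer arrays, or more probes, are part of these alternatives. Without the fat array of each genotype highest in macrophage markers the counts were 530 and 554. Leaving out 1 array gave 318 to 670 in controls and 305 to 677 in knockouts, and leaving out 1 slide gave 149 to 346 and 74 to 344. For knockout against control in fat, the 1 gene became 0 with no background correction, normexp with offset 50, the authors' values, the mean of a gene's probes, only the 2 groups compared, array weights, eBayes with trend and robust, and the replicate block within each tissue. It became 2 with no filter on dim probes (Slc10a7 and C030034I22Rik) and with every kept probe tested, and 3 without the fat array of each genotype highest in macrophage markers (Slc10a7, Cd300lg and Muc13). Leaving out 1 array gave 0 to 3 and leaving out a slide 0. In spleen, 1 gene was called with no filter on dim probes (Dtwd1, adjusted p 0.0364). The difference between tissues and the average each gave 1 (Cd300lg) without those same fat arrays. Leaving out 1 array or slide gave 0 in these 3 comparisons. The cause was not tested for these changes. Of 133 called gene values 51 kept their call in every alternative that followed named genes, 82 lost it in at least 1, 18 others gained one, and 0 reversed. Of 34 called list shifts 15 kept their call in every alternative with a list test, 19 lost it, 25 others gained one, and 0 reversed. Neither tally covers the 2-group fits or the alternatives chosen after the result was seen. Among the genes named by the rule and the lists, the block for the slide changed only the calls of Relb, Srebf2 and Nt5e and of the MHC class II list in the average. Most probes were not detected in a given array: 27.0 to 40.9% were detected, and fold changes near background are not exact.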

Other observations

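The tests in this part were chosen after the results were seen. The fat arrays differed from each other in which other cells' markers they carried. Adipocyte markers averaged 7.28 and 8.06 on the log2 scale in fat control arrays 1 and 2 but 5.84 in array 3, and 7.50, 7.99 and 5.84 in the fat knockout arrays. Stromal and mesothelial markers (6.26, 6.49 and 4.87 in controls, 5.56, 7.35 and 5.16 in knockouts), endothelial markers (6.07, 7.01 and 5.29, then 5.99, 6.90 and 5.33) and granulocyte and mast cell markers (5.94, 7.36 and 5.43, then 6.11, 6.90 and 5.31) had the same order, lowest on slide 3. Markers of B cells (5.28, 5.35 and 7.27), of dendritic cells (6.23, 6.14 and 7.63) and of CD8 and NK cells (6.10, 5.99 and 7.58) were instead highest in fat control array 3, which also had the highest macrophage marker mean (9.28).

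The adipose Treg list averaged 9.29, 8.69 and 9.22 in the fat controls and 9.28, 9.21 and 9.46 in the fat knockouts, against 5.93 to 6.17 in spleen controls and 5.88 to 6.26 in spleen knockouts. Its standard deviation was 0.331 in fat and 0.135 in spleen in controls, and 0.126 and 0.205 in knockouts. The lowest fat value was that of fat control array 2, which also had the lowest macrophage marker mean of the fat arrays (6.83). Slopes on the macrophage markers differed within the adipose Treg list, with quartiles of −0.18 and 0.40 over the 16 genes that rose. Of these, 3 had a slope of at least 0.5 (Cd36 0.81, Plin2 0.73 and Prdm1 0.58), Cxcl2 lay just under it (0.496), and 6 had a slope of 0 or less.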
